A study of Mus musculus with 332 samples.

How the data were processed

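The series followed the tibialis anterior muscle of C57BL/6J mice after a freeze injury, made by holding a metal probe chilled on dry ice against the muscle of the left leg for 10 s, with the right leg as control. Of the 332 samples, 262 chromatin immunoprecipitation (ChIP) libraries, 10 RNA libraries of satellite cells (the stem cells of muscle, MuSC) and 9 miRNA samples had values here, and 51 samples, which include the inputs, were not analysed here. Groups, times and animal numbers were taken from the labels. For 14 H3K4me1 and H3K4me3 samples of 28 d the labels disagreed. The description of 8 injured samples names 21 d, and that of 6 control samples calls them injured. These samples were grouped by the characteristics and title.

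The MuSC table holds TPM, a share of transcripts with gene length divided out, as deposited by the authors for cDNA amplified from 10 ng of RNA per the labels' protocols. The aligner and annotation behind it are not given in the sources used here, and its key names a pair of read sets per library with the word unmapped, without saying what the reads were not mapped to. TPM keeps no sequencing depth, so the depth of these libraries is unknown and no counting interval was given. Of 24518 entries, 27 carried a date in place of a symbol and were left out, and 15665 of the remaining 24491 genes reached 1 TPM in at least 2 libraries and were tested. The miRNA table holds a normalized signal per mature miRNA deposited by the authors, and the submitters' processing notes name DESeq. All 9189 of its values (100%) were whole multiples, within 0.001, of what 1 read was worth in their library, so whole reads were recovered, from 165753 to 1980895 per library. The labels disagree on whether the miRNA came from whole muscle or from satellite cells.

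The ChIP files are peak lists called per library with MACS2 on mm9, per the submitters' processing notes. They give each peak a −log10 q-value or a score derived from it, as deposited by the authors. H3K27ac and H3K4me3 files hold peak summits and H3K4me1 files hold broad regions. The 9 files of the 72 h control legs of H3K27ac (5 libraries) and H3K4me3 (4 libraries) hold broad regions instead of summits. They were left out of these comparisons, a decision made after the result with them had been seen, and both results are given. Repeat lanes of a leg were averaged on the log10 scale, and the 7 d numbers 04 and 04B were joined. Scores were used only to rank or filter peaks within a list.

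RNA was tested on log2(TPM + 1) with limma 3.58.1 (trended empirical Bayes) in R 4.3.3 with data.table (version 1.17.8), over all 10 libraries so that they share an estimate of spread, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05, two-sided. Fold changes are differences on that log2 scale, which understates changes of low genes. The 23 gene lists were quiescence and Notch, immediate early response, DNA replication, mitosis, myogenic commitment and fusion, embryonic and neonatal sarcomere, adult sarcomere, inflammatory cytokines, interferon response, extracellular matrix, oxidative phosphorylation, glycolysis, ribosome biogenesis, histone and DNA modifiers, and markers of macrophages, neutrophils, lymphocytes, endothelium, fibro-adipogenic progenitors, pericytes, Schwann cells, erythroid cells and adipocytes. Lists with at least 5 kept genes were tested with limma's camera at a preset correlation of 0.01, adjusted over all 110 list tests, and repeated with an estimated correlation and with fry. Each list count is over all genes tested, followed where it differs by the count adjusted over the list alone. Each miRNA group holds 1 sample, so log2 ratios of (value + 1) to the 3 h control were described for the 169 miRNAs with a mean of at least 50, with 95% intervals from the recovered reads that cover counting error only. The 7 miRNA lists (muscle-enriched, blood and immune, mir-17-92 and related, mir-29 with mir-199 and mir-214, the Dlk1-Dio3 and H19 loci, vascular, let-7) are given as the percentile of their median among 10000 random lists matched on mean level.

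Peak numbers per leg were compared on log10(peaks + 1) within 3 phases (3 to 10 h, 24 to 72 h, 7 to 28 d) by two-sided permutation tests, exact where a group had fewer than 10 legs and with 100000 resamples otherwise, adjusted over the 9 comparisons. No gene annotation of mm9 was used here, so the planned promoters were replaced, as laid down in advance, by regions made from summits within 1 kb of each other and named by mm9 position. Only H3K27ac libraries with at least 5000 summits and H3K4me3 libraries with at least 10000 entered, each with that many of its highest summits. Each leg entered with 1 library, the repeat lane with the most summits. At 7 to 28 d this left 4 injured and 4 control H3K27ac libraries, from 17 and 14 legs. Each region marked in at least 3 libraries and missing in at least 3 was compared by a two-sided Fisher's exact test. Left and right legs with the same animal number come from the same animal per the labels. The deviations of such legs from their group means correlated at 0.197 over 22 pairs for H3K27ac, 0.593 over 25 pairs for H3K4me3 and 0.438 over 29 pairs for H3K4me1. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

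The comparisons, tests, lists and alternatives were fixed before the data were examined, except where the text says otherwise. Genes named were, per comparison, the 5 with the largest rise and the 5 with the largest fall among those past the threshold with a mean of at least 10 TPM in the higher group and no overlap of libraries, up to 4 changed members of each list, all members of lists of 9 or fewer, and Pax7, Myf5, Myod1, Myog, Myh3, Cdkn1a, Mki67 and Spry1. Cxcl2 and Cxcl5 at 24 h and Ezh2 at 72 h are list members named outside this rule. For miRNA the rule gave the 5 highest and 5 lowest ratios per time and the list members, and for ChIP the 10 regions with the smallest p in each direction. Tested on simulated data for 168 h against 72 h (15665 genes, 200 changed), the RNA test called 6% of genes changed by 0.5 log2, 46% at 1, 78% at 2 and 50% at -1, with 10 unchanged genes called. Each gene was simulated with the same spread at every time. Real replicates correlated less at 3 h and 24 h than at 72 h and 168 h, so these shares need not hold for the real comparisons. The region test called 97% of 200 changed regions among 5000 and 6 unchanged regions, simulated for the 14 injured and 8 control libraries of H3K4me3 at 7 to 28 d. The changed regions were set to be marked in nearly all injured and almost no control libraries. Smaller differences and comparisons with fewer libraries were not simulated. The miRNA read test was also tested on simulated data (169 miRNAs, 40 changed, 72 h against the 3 h control), and 1 unchanged miRNA was called. Alternatives covered the pseudocount, the filter, median-of-ratios and quantile scaling, the samples in the fit, left-out libraries, the replicate number as a block, peak scores, list lengths, merging distances, flow cells and pairs of legs.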

Results

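The data covered gene expression, miRNA and histone marks after freeze injury of the mouse tibialis anterior. RNA of satellite cells was measured at 3, 24, 48, 72 and 168 h after injury in 2 libraries per time, 10 in all, with no uninjured group in the labels. Small RNA was measured in 1 sample each at 3 h, 10 h, 72 h, 7 d, 14 d, 21 d and 28 d after injury and in controls of 3 h and 28 d. ChIP-seq of H3K27ac, a mark of active promoters and enhancers, H3K4me3, a mark of active promoters, and H3K4me1, a mark of enhancers, was made from injured and control legs at 3, 10, 24, 48 and 72 h and at 7, 14, 21 and 28 d. The H3K27ac set held 53 libraries of 39 injured legs and 32 of 29 control legs, the H3K4me3 set 51 of 39 and 36 of 31, and the H3K4me1 set 54 of 39 and 36 of 31. Nothing in the labels says that RNA replicates came from separate animals, so their p-values measure the spread between these samples, which may be technical.

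TPM values summed to between 996853 and 997529 per RNA library, and the sequencing depth behind them is unknown. Genes at 1 TPM or more numbered 13800 and 13809 at 3 h, 12459 and 12468 at 24 h, 10079 and 10071 at 48 h, 12848 and 12834 at 72 h and 12384 and 12395 at 168 h. Replicates correlated across genes at 0.947 (3 h), 0.917 (24 h), 0.986 (48 h), 0.993 (72 h) and 0.996 (168 h). Libraries of different times between 3 h and 48 h correlated at 0.81 to 0.87, those of 72 h with those of 168 h at 0.98, and those of the earlier with those of the later times at only 0.51 to 0.65. Genes are not independent replicates. The 48 h libraries stood apart. Of 342 genes at 500 TPM or more at 72 h and 168 h, 71 lay under 5 TPM in both 48 h libraries, against 2 at 3 h and 0 at 24 h. Of the ribosomal protein genes, which every cell uses, 22 of 78 lay under 10 TPM at 48 h. Those over 500 TPM numbered 33 at 3 h, 34 at 24 h and 35 at 48 h, against 70 at 72 h and 72 at 168 h. How the earlier and the later libraries were made is not given in the sources used here. A difference in their making cannot be told apart from time where 72 h or 168 h is set against 3 h. A value listed at 0 is therefore given per library and without a fold.

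The time course asked how the satellite cell transcriptome moved through regeneration. Myogenin (Myog), the transcription factor of myoblast differentiation, lay at 7.337 and 4.346 TPM at 3 h and at 1104 and 1126 TPM at 72 h. Pax7, the transcription factor of quiescent satellite cells, lay at 12.85 and 15.52 TPM at 3 h and at 1.382 and 1.274 TPM at 72 h. Over the 5 times, 13426 of 15665 genes changed (limma's moderated F-test, adjusted p under 0.05). Rescaling moved the median log2 change of all genes, which was -0.12 at 24 h, -0.41 at 48 h, 0.06 at 72 h and -0.07 at 168 h against 3 h. With median-of-ratios scaling it was -0.02, -0.15, 0.23 and 0.19, and with quantile normalization 0.06, 0.31, 0.03 and 0.01. The list calls that held with an estimated correlation were 23 of 58. They were, against 3 h, immediate early genes at 24, 72 and 168 h, adult sarcomere, inflammatory, macrophage and erythroid genes at 24 h, embryonic sarcomere genes at 48 h, mitosis, oxidative phosphorylation and glycolysis at 72 and 168 h, and ribosome biogenesis at 168 h. For 168 h against 72 h they were immediate early, adult sarcomere, matrix, oxidative phosphorylation, glycolysis, ribosome biogenesis, endothelial and fibro-adipogenic genes.

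**Figure D1:**
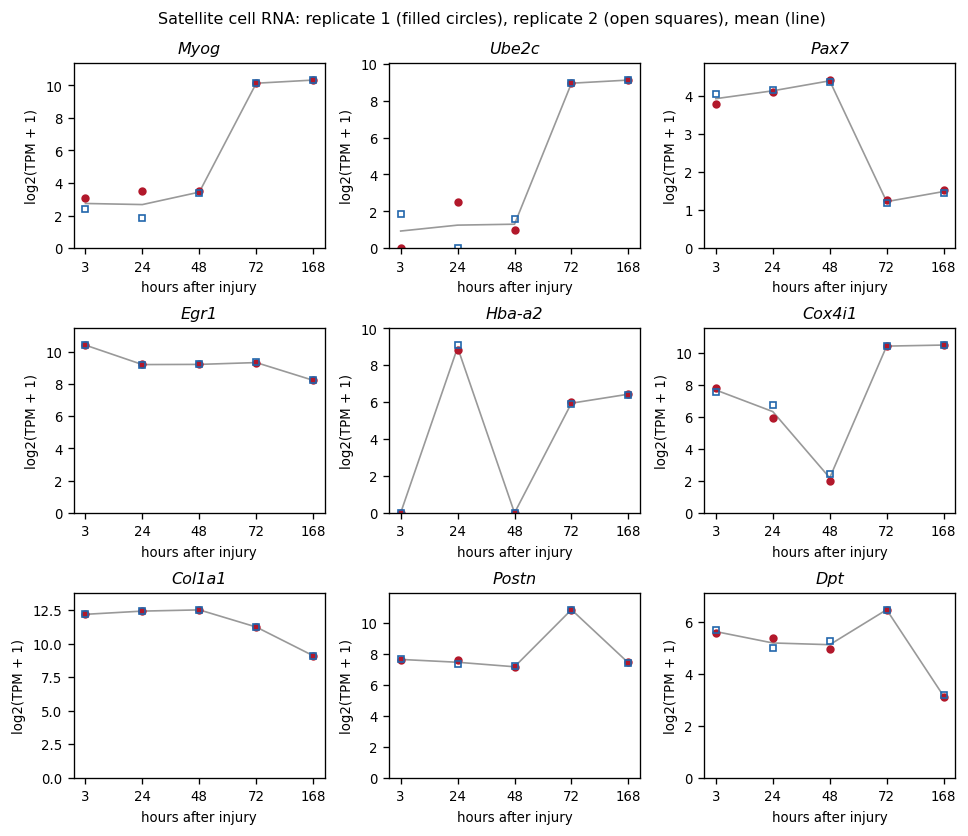
TPM of 9 genes in the satellite cell libraries on a log2(TPM + 1) axis against hours after injury, with filled circles for replicate 1, open squares for replicate 2 and a line through the means. Myog and Ube2c lay higher at 72 h and 168 h than at the earlier times, Pax7 lower, Hba-a2 was listed at 0 at 3 h and 48 h, and Postn lay at 1828 and 1817 TPM at 72 h.

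Between 3 h and 24 h, globin, chemokine and myeloid transcripts were higher and contractile and immediate early transcripts lower. Hba-a2, which encodes a haemoglobin chain of red cells, was listed at 0 in both 3 h libraries and at 448.5 and 548.8 TPM at 24 h, and Hba-a1 rose by 4.78 ± 0.09 (log2, SE, n = 2 per group). The calprotectin genes of neutrophils, S100a8 (56.29 and 69.48 TPM) and S100a9 (27.9 and 55.1 TPM), and Cd14, a receptor of monocytes for bacterial lipopolysaccharide (62.57 and 29.7 TPM), were likewise listed at 0 in both 3 h libraries. In all, 5371 genes changed, 1824 higher and 3547 lower. These calls and SEs, like all against 3 h, rest on the spread over all 10 libraries. Replicates correlated less at 3 h (0.947) and 24 h (0.917) than at 72 h (0.993) and 168 h (0.996). The SEs may therefore understate the spread at 3 h and 24 h, and a fit of only these 2 groups called fewer genes, as given below. Without the 48 h libraries, left out after the data had been seen, 4952 genes changed, 1612 higher and 3340 lower. The share of higher genes among the calls was 34%, and 43.4% with median-of-ratios and 56.4% with quantile scaling.

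Of 18 inflammatory cytokine genes, 10 rose and 2 fell at 24 h (adjusted over the list alone, 12 and 3; camera adjusted p = 1.12e-05). Cxcl2, a neutrophil attractant, rose by 2.69 ± 0.15 and Cxcl5, another, by 2.16 ± 0.30, whereas Cxcl10, an interferon-induced chemokine, had a log2 change of -3.04 ± 0.66. Of 14 macrophage genes 7 rose and 0 fell (adjusted p = 6.64e-06), among them Fcer1g, an Fc receptor subunit, which was listed at 0 at 3 h and stood at 27.32 and 60.48 TPM at 24 h. Of 6 erythroid genes 4 rose (5 adjusted over the list alone; adjusted p = 3.03e-05), and of 6 neutrophil genes 3 rose (adjusted p = 0.00523, and adjusted p = 0.112 with an estimated correlation). Adult sarcomere genes fell in 17 of 20 cases, 18 adjusted over the list alone (adjusted p = 6.84e-08), with Mb, the oxygen store of muscle, at -2.26 ± 0.12 and Casq1, the calcium-binding protein of the sarcoplasmic reticulum, at -1.60 ± 0.13. Immediate early genes fell in 14 of 19 cases (adjusted p = 7.17e-05), among them Ier2 at -2.39 ± 0.24 and Socs3, an inhibitor of cytokine signalling, at -1.73 ± 0.09. With quantile normalization 1 member of each of these 2 lists rose, and with median-of-ratios scaling 2 immediate early genes did.

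Some cell cycle genes rose at 24 h. Of 20 DNA replication genes 8 rose (adjusted p = 9.44e-05, and adjusted p = 0.106 with an estimated correlation), with Mcm5, a subunit of the replicative helicase, at 1.71 ± 0.26. Of 20 mitosis genes 7 rose (adjusted p = 0.000207 and 0.0615), with Cdk1, the mitotic kinase, at 2.06 ± 0.40, and 15 rose with quantile normalization. Ribosome biogenesis genes rose in 5 and fell in 1 of 16 cases (6 and 1 adjusted over the list alone; adjusted p = 0.00824 and 0.0708). Schwann cell markers fell in 5 of 6 cases (adjusted p = 0.00394, and adjusted p = 0.07 with an estimated correlation), with Mbp, the myelin basic protein, at -3.36 ± 0.20. Pericyte genes fell in 5 of 8 cases without a list call (adjusted p = 0.115). Among the myogenic regulators, Myod1 had a log2 change of -1.15 ± 0.35 and an adjusted p of 0.034 by limma, Myf5 rose by 0.43 ± 0.06, and Pax7 at 0.21 ± 0.13 did not pass the test. The largest rises included Amd2, a near copy of Amd1 whose reads it could share (7.80 ± 0.37), and the largest falls were short RNA genes such as Snord69 and Mir122, listed at 0 at 24 h. A fit of only these 2 groups called 1227 genes, and a fit of the 3, 24 and 48 h libraries 2705.

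At 48 h compared with 3 h, 6 of 9 embryonic and neonatal sarcomere genes were higher and many abundant transcripts lay at or near 0. Among them Tnnc1, the slow troponin C, rose by 1.69 ± 0.09 (log2, SE, n = 2 per group) and Myh8, the neonatal myosin heavy chain, by 1.95 ± 0.22. Cst3, a secreted protease inhibitor made by most cells, lay at 1258 and 1385 TPM at 3 h and was listed at 0 in both 48 h libraries, as was Mb after 607.4 and 651.8 TPM. In all, 7955 genes changed, 1766 higher and 6189 lower, so 22.2% of the calls were higher, and 38.8% with median-of-ratios and 63.5% with quantile scaling. This comparison cannot be made without the 48 h libraries.

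Embryonic and neonatal sarcomere genes rose in 6 and fell in 0 of 9 cases, 7 adjusted over the list alone (adjusted p = 5.83e-06), with Tnnt1, the slow troponin T, at 1.75 ± 0.31. Adult sarcomere genes moved both ways, 3 up and 11 down of 20 (adjusted p = 0.0952), and 5 rose with either other scaling. Oxidative phosphorylation genes fell in 16 and rose in 2 of 20 cases (adjusted p = 0.0165, and adjusted p = 0.0844 with an estimated correlation), with the cytochrome oxidase subunits Cox4i1 at -5.48 ± 0.27 and Cox5b at -6.50 ± 0.61, in libraries that listed many housekeeping genes near 0. With median-of-ratios scaling 8 members of that list fell and 3 rose, and with quantile normalization 16 fell and 0 rose. Immediate early genes fell in 13 and rose in 1 of 19 cases (14 and 1 adjusted over the list alone; adjusted p = 0.011 and 0.074), although with median-of-ratios scaling 6 rose and 11 fell. All 6 Schwann cell markers fell (adjusted p = 0.00127, and adjusted p = 0.0594 with an estimated correlation), with Mbp at -6.02 ± 0.20.

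Inflammatory genes fell in 11 and rose in 2 of 18 cases without a list call (adjusted p = 0.0845), and Ccl2, the monocyte attractant, lay at 44.18 and 40.45 TPM at 3 h and was listed at 0 at 48 h. Macrophage genes were mixed, 2 up and 3 down of 14, or 5 up and 2 down with quantile normalization, and Lyz2, the lysozyme of myeloid cells, had a log2 change of -5.86 ± 0.18. The DNA replication list was called higher (adjusted p = 0.011, and adjusted p = 0.249 with an estimated correlation) with 4 members up and 4 down (4 and 3 adjusted over the list alone). It had 9 up and 2 down with median-of-ratios scaling and 11 up and 0 down with quantile normalization. The mitosis list was likewise called higher (adjusted p = 0.00625 and 0.106) with 4 up and 1 down, and 7 or 15 rose with these scalings. Myod1 was lower, at -3.54 ± 0.35, while Pax7 rose by 0.47 ± 0.13 and Myf5 by 0.50 ± 0.06. Because the 48 h libraries listed many abundant genes near 0, the lower values of Myod1, Lyz2 and Ccl2 are not shown to be regulation. Several of the largest changes were in predicted genes with near-identical copies, whose reads could not be told apart, among them Gm10591 and Gm13304, which share the values 826 and 911.2 TPM at 3 h and 0 at 48 h.

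By 72 h all 20 mitosis genes had risen above 3 h, as had several genes of myogenic differentiation and fusion, although the myogenic list was not called (adjusted p = 0.428). Myog rose by 7.38 ± 0.50, Tmem8c, the fusion protein myomaker, by 7.00 ± 0.70, and Chrng, the foetal acetylcholine receptor subunit, by 4.99 ± 0.50 (log2, SE, n = 2 per group). Gm7325, the fusion peptide myomixer, was listed at 0 in both 3 h libraries and at 94.04 and 106.3 TPM at 72 h. Gal, the neuropeptide galanin, rose by 9.79 ± 0.96, the largest rise of a gene not at 0 at 3 h among those named. Pax7 had a log2 change of -2.70 ± 0.13, Myf5, a regulator of satellite cells and myoblasts, of -4.30 ± 0.06, and Spry1, an inhibitor of growth factor signalling in quiescent cells, of -2.26 ± 0.10. In all, 11262 genes changed, 5753 higher and 5509 lower, and without the 48 h libraries 10967, 5602 higher and 5365 lower. Beside these changes, ribosomal protein genes over 500 TPM went from 33 to 70 of 78.

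All 20 mitosis genes rose at 72 h (adjusted p = 6.23e-07), with Ube2c, a ubiquitin enzyme of mitotic exit, at 8.03 ± 0.87, Ccnb1, cyclin B, at 7.14 ± 0.24 and Mki67, a proliferation marker, at 2.47 ± 0.21. DNA replication genes rose in 19 of 20 cases (adjusted p = 8.23e-06, and adjusted p = 0.0776 with an estimated correlation), with Mcm5 at 4.91 ± 0.26. Of 16 myogenic genes 9 rose and 6 fell, with Myod1 at 2.38 ± 0.35, Cdkn1a, an inhibitor of the cell cycle, at 1.27 ± 0.18. The embryonic sarcomere list split, 5 up and 4 down of 9, with Myh3, the embryonic myosin heavy chain, at 3.65 ± 0.38 and Tnnc1 at -0.82 ± 0.09. Adult sarcomere genes fell in 17 and rose in 1 of 20 cases (adjusted p = 5.37e-06, and adjusted p = 0.0537 with an estimated correlation), with Myh7, the slow myosin heavy chain, at -5.19 ± 0.15. Immediate early genes fell in 17 and rose in 1 of 19 cases (adjusted p = 2.9e-06), with Klf4 at -2.41 ± 0.13 and Btg2, an inhibitor of proliferation, at -2.37 ± 0.06. Quiescence and Notch genes fell in 9 and rose in 3 of 17 cases without a list call (adjusted p = 0.263), among them Foxo3 at -3.75 ± 0.16 and Calcr, the calcitonin receptor, at -2.44 ± 0.22, and with median-of-ratios scaling 6 members rose.

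Metabolic and growth genes were higher at 72 h than at 3 h, where a difference in library making cannot be told apart from time. Oxidative phosphorylation genes rose in 19 of 20 cases (adjusted p = 5.69e-06), Ndufa4 at 2.93 ± 0.36, although 1 member fell with quantile normalization. Glycolysis genes rose in 13 and fell in 1 of 16 cases (adjusted p = 9.44e-05), with the enolase gene Eno1 at 4.03 ± 0.17. Ribosome biogenesis genes rose in 12 and fell in 1 of 16 (adjusted p = 0.0014, and adjusted p = 0.0537 with an estimated correlation), with Nop2, a methyltransferase of ribosomal RNA, at 4.21 ± 0.35. Of 14 macrophage genes 11 rose and 2 fell (adjusted p = 0.00768 and 0.0708), and the complement gene C1qb was listed at 0 in both 3 h libraries and at 97.54 and 102.5 TPM at 72 h. Inflammatory genes rose in 11 and fell in 1 of 18 cases (adjusted p = 0.0281 and 0.106). Matrix genes rose in 12 and fell in 7 of 20 cases without a list call (adjusted p = 0.263), with Postn, a matrix protein of healing tissue, at 3.21 ± 0.08. Endothelial genes fell in 7 of 10 cases (adjusted p = 0.00625 and 0.0708), with Cldn5, a tight junction protein, at -3.30 ± 0.06, and all 6 Schwann cell genes fell (adjusted p = 0.00351 and 0.0693). The largest falls included Gm1821, a ubiquitin pseudogene whose reads could come from its parent genes (-10.77 ± 0.07), and Hspa1l (-9.64 ± 0.09), which has near copies.

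At 168 h compared with 3 h, mitosis, metabolic and ribosome biogenesis genes were higher and 12 of 20 matrix genes lower, the matrix list without a call when the correlation was estimated (adjusted p = 0.141). Col1a1 and Col1a2, the chains of type I collagen, had log2 changes of -3.09 ± 0.02 and -3.26 ± 0.01, and Mfap5, a microfibril protein, of -4.68 ± 0.07 (SE, n = 2 per group). Myog rose by 7.58 ± 0.50, Ube2c by 8.20 ± 0.87 and Gal by 10.18 ± 0.96, while Calcr had a log2 change of -3.37 ± 0.22 and Hes1, a target of Notch, of -2.57 ± 0.08. In all, 11447 genes changed, 5488 higher and 5959 lower, and without the 48 h libraries 11150, 5324 higher and 5826 lower, beside 72 of 78 ribosomal protein genes over 500 TPM at 168 h. Mitosis genes rose in 20 of 20 cases (adjusted p = 3.73e-07) and DNA replication genes in 18 of 20 (adjusted p = 2.7e-06, and adjusted p = 0.0708 with an estimated correlation). Immediate early genes fell in 17 of 19 cases (adjusted p = 5.39e-07), although 1 member rose with median-of-ratios scaling, and adult sarcomere genes fell in 17 and rose in 1 of 20 (adjusted p = 4.42e-06 and 0.0537), with Mb at -3.73 ± 0.12. Quiescence and Notch genes fell in 10 and rose in 4 of 17 cases without a list call (adjusted p = 0.154).

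Oxidative phosphorylation genes rose in 19 of 20 cases at 168 h (adjusted p = 1.15e-06), with Cyc1, cytochrome c1, at 2.77 ± 0.11. Glycolysis genes rose in 13 of 16 with 2 lower (adjusted p = 6.18e-05) and ribosome biogenesis genes in 13 of 16 with 1 lower (14 and 1 adjusted over the list alone; adjusted p = 0.000183). Matrix genes fell in 12 and rose in 3 of 20 cases, 13 and 3 adjusted over the list alone (adjusted p = 0.00625, and adjusted p = 0.141 with an estimated correlation), and with median-of-ratios scaling 7 rose and 9 fell. Markers of cells that a satellite cell isolate can hold moved beside them. Fibro-adipogenic genes fell in 7 and rose in 1 of 9 cases (adjusted p = 0.0079 and 0.232), with the proteoglycan gene Dcn at -3.17 ± 0.03. Endothelial genes fell in 9 of 10 (adjusted p = 0.00191 and 0.0612), with Tek, the angiopoietin receptor, at -3.89 ± 0.12. Schwann cell genes fell in 6 of 6 (adjusted p = 0.00625 and 0.0716) and pericyte genes in 6 of 8 (adjusted p = 0.0643), with 2 pericyte genes higher with median-of-ratios scaling. Macrophage genes rose in 11 and fell in 2 of 14 cases (adjusted p = 0.00353 and 0.0655), neutrophil genes rose in 4 of 6 (adjusted p = 0.067) and erythroid genes in 3 of 6 (adjusted p = 0.0503).

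From 72 h to 168 h, 18 of 20 matrix and 7 of 9 fibro-adipogenic genes fell, while 4 of 16 myogenic and 0 of 20 mitosis genes passed the test. Postn, at 1828 and 1817 TPM at 72 h, lay at 171.5 and 165.2 TPM at 168 h (log2 change -3.43 ± 0.08, SE, n = 2 per group), Aspn, a small proteoglycan, had a log2 change of -3.75 ± 0.09, and Col1a1 of -2.14 ± 0.02. Dpt, a matrix protein and marker of fibro-adipogenic progenitors, lay at 87.28 and 86.81 TPM and then at 7.484 and 8.142 TPM (-3.32 ± 0.16). Myog (0.19 ± 0.50), Myod1 (0.35 ± 0.35) and Pax7 (0.26 ± 0.13) did not pass the test. These SEs rest on the spread over all 10 libraries, the earlier times included. A gene that did not pass is therefore not shown to have stayed level. In all, 1265 genes changed, 122 higher and 1143 lower, so 9.6% of the calls were higher, and 35.7% with median-of-ratios and 21.8% with quantile scaling. Without the 48 h libraries 1028 genes changed, 89 higher and 939 lower. A fit of the 4 libraries alone, with 12917 genes tested, called 6888, 2642 higher and 4246 lower. In the fit of all 10 libraries, which gave the 1265 genes, fewer were called when any 72 h or 168 h library was left out. More were called when either 24 h library was left out.

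Matrix genes fell in 18 of 20 cases, 19 adjusted over the list alone (adjusted p = 4.34e-39), with Mmp14, a membrane collagenase, at -2.17 ± 0.06 and Col5a1 at -2.49 ± 0.12. Fibro-adipogenic genes fell in 7 of 9 cases (adjusted p = 1.36e-10), with Mfap5 at -3.10 ± 0.07 and Fbln1 at -0.34 ± 0.05, while Ly6a (-0.10 ± 0.18) and Pi16 (-0.54 ± 0.61) did not pass the test. Pericyte genes fell in 4 of 8 cases, 5 adjusted over the list alone (adjusted p = 2.35e-06, and adjusted p = 0.0655 with an estimated correlation), with Rgs5, a pericyte marker, at -1.63 ± 0.13. Endothelial genes fell in 4 of 10 (adjusted p = 0.000448), with Pecam1 at -0.97 ± 0.13. Immediate early genes fell in 16 of 19 cases, all 19 adjusted over the list alone and 10 with median-of-ratios scaling (adjusted p = 3.4e-20), with Egr1 at -1.10 ± 0.03 and Fos at -0.88 ± 0.04. Adult sarcomere genes fell in 13 of 20, 14 adjusted over the list alone (adjusted p = 5.93e-11), with Pvalb, a calcium buffer of fast fibres, at -1.57 ± 0.15 and Myh4, the fastest myosin heavy chain, at -1.51 ± 0.09. Quiescence and Notch genes fell in 4 of 17 cases, 5 adjusted over the list alone (adjusted p = 0.0153 and 0.11), with Cd34 at -0.80 ± 0.15 and Hes1 at -0.65 ± 0.08, and 2 fell with either other scaling.

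Growth and metabolic lists were higher at 168 h than at 72 h by small amounts. The median log2 change was 0.19 for oxidative phosphorylation, with 2 of 20 members up, 3 adjusted over the list alone (adjusted p = 2.36e-06). It was 0.12 for glycolysis, with 2 of 16 up, 4 adjusted over the list alone (adjusted p = 0.000388), and 0.21 for ribosome biogenesis, with 1 of 16 up (adjusted p = 3.4e-05). With median-of-ratios scaling 9, 5 and 5 members of these lists rose. The DNA replication list was called higher with 0 of 20 members past the test by limma (adjusted p = 0.000313, and adjusted p = 0.126 with an estimated correlation), and 3 with median-of-ratios scaling. So were the macrophage list with 0 of 14 members past it (adjusted p = 0.00127 and 0.0537) and the erythroid list with 0 of 6, 3 adjusted over the list alone (adjusted p = 0.00569 and 0.0708), of which 3 passed with median-of-ratios scaling and 2 with quantile normalization. No mitosis gene passed (0 of 20, adjusted p = 0.0845). Of 16 myogenic genes 1 rose and 3 fell, 2 and 3 adjusted over the list alone (adjusted p = 0.433), with Rapsn, a clustering protein of acetylcholine receptors, at 0.34 ± 0.07 and Mef2c at -0.70 ± 0.12. The largest rises were in short or repeated genes, among them Mir8114 (1.34 ± 0.16) and the histone gene Hist1h4c (1.07 ± 0.17), which near copies could share reads with.

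The miRNA samples asked which miRNAs moved after injury, each as a ratio to the 3 h control sample with no replicate. miR-223-3p, a miRNA of neutrophils and monocytes, lay above the 3 h control by 2.45 (log2) at 3 h, 4.64 at 10 h (95% counting interval 4.23 to 5.23) and 4.88 at 72 h (4.47 to 5.46), by 2.08 at 7 d and at -0.33 at 28 d. miR-142-5p, a miRNA of blood cells, peaked at 4.49 at 72 h, and miR-21a-5p, widely induced in inflamed tissue, at 3.42 (3.38 to 3.46). miR-206-3p, the skeletal muscle miRNA of regenerating fibres, was at -1.33 at 10 h, 3.03 at 7 d, 3.85 at 14 d (3.64 to 4.08) and 3.21 at 28 d, against -0.71 in the 28 d control. miR-31-5p, with 5 reads in the 3 h control, stood at 5.10 at 72 h (4.30 to 7.20) and 5.64 at 28 d, and miR-34c-5p at 3.73 and 2.98. miR-133a-3p, a miRNA of mature muscle, was lowest at 72 h, at -1.80.

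Among 169 miRNAs, those at least 2-fold higher and lower than in the 3 h control numbered 12 and 15 at 3 h, 11 and 12 at 10 h, 33 and 38 at 72 h, 27 and 25 at 7 d, 29 and 23 at 14 d, 33 and 60 at 21 d and 26 and 27 at 28 d. The 28 d control gave 8 and 12, with an SD of log2 ratios of 0.83, as the background between 2 controls. An exact binomial test on the recovered reads, added after the data had been seen, called 119 of them at 3 h and 146 at 72 h, but also 120 in the 28 d control, and compares those libraries, not the conditions. The blood and immune list (9 miRNAs) had a median of 0.56 at 10 h, above 98.9% of random lists, 0.97 at 72 h (95.8%) and 1.19 at 7 d (99.5%), against -0.10 in the 28 d control (41.8%). Muscle-enriched miRNAs (7) had a median of 0.51 at 14 d (96.0%) and 0.76 at 21 d (98.6%), but -0.74 at 72 h (47.8%). The mir-29, mir-199 and mir-214 list (7), miRNAs of fibroblasts, stood at 0.69 at 7 d (97.7%), and the list of mir-17-92 and related miRNAs (7, among them miR-16-5p and miR-25-3p of other clusters) at 0.88 at 72 h (89.9%). The 21 d library held only 165753 reads, 36.5% of them miR-22-3p, so low miRNAs were least precise there, and near copies such as miR-199a and miR-199b share reads.

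**Figure D2:**
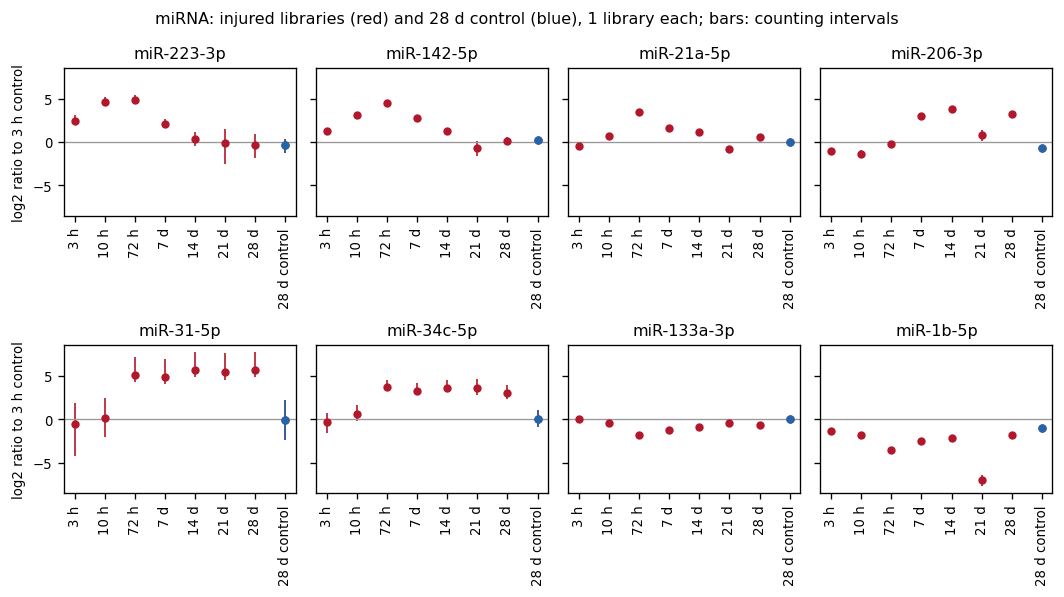
Log2 ratio of 8 miRNAs to the 3 h control sample against time after injury (red, injured; blue, 28 d control), 1 sample per point, with bars for the 95% counting interval. miR-223-3p reached 4.88 at 72 h, miR-206-3p 3.85 at 14 d and miR-31-5p 5.64 at 28 d.

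The ChIP libraries asked how active chromatin differed between injured and control legs. At 24 to 72 h, injured legs held a geometric mean of 4550 H3K27ac peaks (SD of log10 0.888, n = 13) and control legs 30737 (0.151, n = 3), a log10 difference of -0.830 that did not pass the exact permutation test (p = 0.139, adjusted p = 0.335). The lowest injured leg, replicate 2 at 24 h, held only 12 peaks and pulls the injured mean down, and the difference without it was not computed. With the 72 h control files of broad regions, the difference was -0.783 (7 control legs, exact permutation p = 0.0183, adjusted p = 0.0824), lower in the injured leg of 6 of 6 pairs. H3K4me3 in the same phase gave 12994 and 24569 peaks (SD 0.376, n = 13, and 0.211, n = 5), a difference of -0.277 (exact permutation p = 0.149, adjusted p = 0.335). Injured replicate 2 at 24 h was again the lowest injured leg, at 939 H3K4me3 peaks, and was likewise not left out. H3K4me1 gave 932 and 2474 regions (0.555, n = 13, and 0.605, n = 8), a difference of -0.424 (exact permutation p = 0.12, adjusted p = 0.335) that turned to 0.0322 with only regions scored at least 5. Of the H3K4me1 libraries in that phase, 25 of 34 held under 1100 regions, and the median share of regions on unplaced sequence was 32.2%. Within flow cells these differences were -0.769, -0.285 and -0.478.

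At 3 to 10 h, with 9 injured and 8 control legs per mark, H3K27ac gave 2676 and 1288 peaks (log10 difference 0.317, exact permutation p = 0.585, adjusted p = 0.744). H3K4me3 gave 1985 and 2250 peaks (-0.054, exact permutation p = 0.916, adjusted p = 0.916) and H3K4me1 1653 and 387 regions (0.630, exact permutation p = 0.225, adjusted p = 0.405, higher in the injured leg of 7 of 8 pairs). The SD of log10 lay between 0.86 and 1.243 in these groups, and the values within flow cells were 0.928, -0.030 and 0.768. At 7 to 28 d, H3K4me1 gave 648 regions in 17 injured legs and 277 in 15 control legs (SD of log10 0.293 and 0.537), a difference of 0.368 (permutation p = 0.0136, adjusted p = 0.122) that was 0.389 within flow cells and 0.393 in paired legs (p = 0.0533), higher in 9 of 14 pairs. Of the libraries behind it, 37 of 38 held under 1100 regions, with a median of 32.1% on unplaced sequence. Leaving out the 28 d libraries whose labels disagree, chosen after the data had been seen, it was 0.307 (13 and 12 legs, permutation p = 0.0707). H3K27ac gave 1673 and 2147 peaks (-0.108, permutation p = 0.661, adjusted p = 0.744, 17 and 14 legs), at -0.018 within flow cells and 0.095 in paired legs. H3K4me3 gave 10615 and 6655 (0.203, permutation p = 0.383, adjusted p = 0.575, 17 and 15 legs), at 0.290 within flow cells. None of the 9 differences passed the adjustment.

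**Figure D3:**
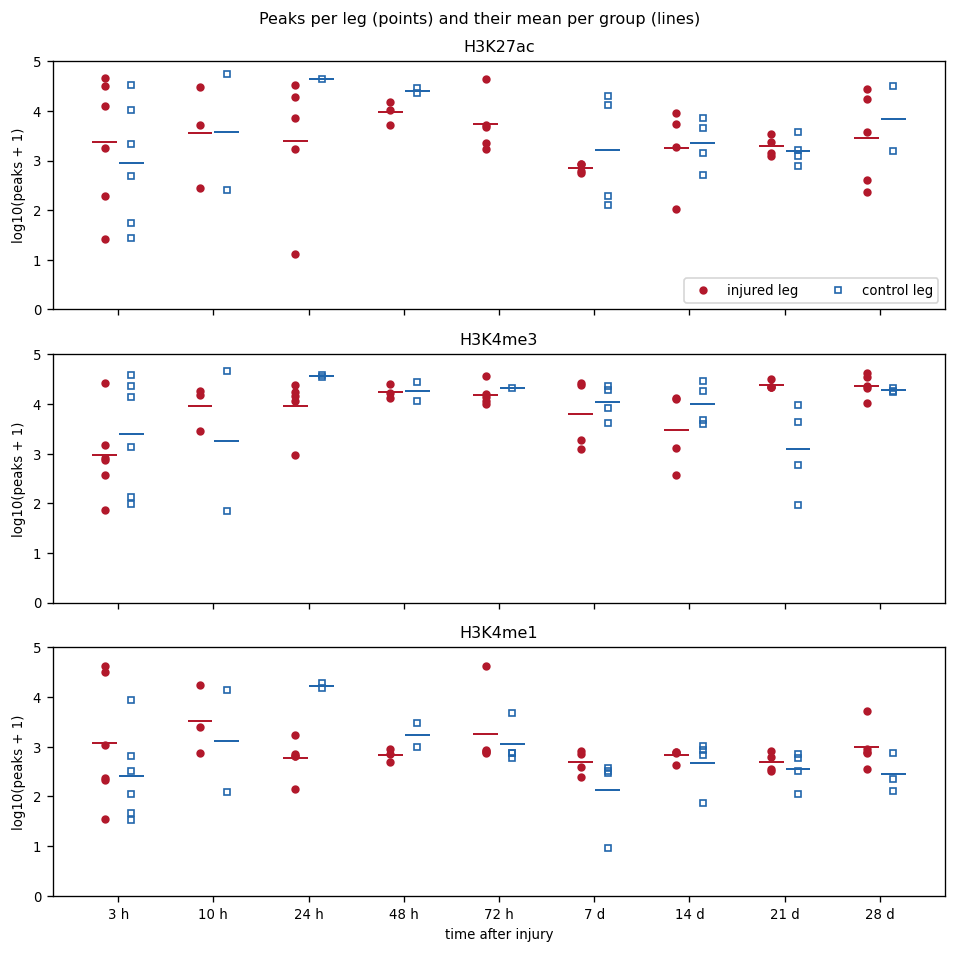
Peaks or regions per leg, as log10(peaks + 1), against time after injury for H3K27ac, H3K4me3 and H3K4me1 (red, injured; blue open, control; lines, means), without the files of broad regions. At 24 to 72 h the 3 H3K27ac control legs lay between 22404 and 44666 peaks and the 13 injured legs between 12 and 43929.

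Regions were compared at equal list lengths, and Fisher's exact test called 0 regions in each of the 6 comparisons of mark and phase. In 4 of them almost no region could have passed the adjustment, since the smallest possible p was 0.0179, 0.00606 and 0.0286 for H3K27ac in order of phase and 0.0286 for H3K4me3 at 3 to 10 h, so their counts of 0 say little. For H3K4me3 at 24 to 72 h, 5908 regions were tested in 12 injured and 5 control libraries, of which 196 were marked more and 248 less often in injured legs at an unadjusted p under 0.05 (smallest adjusted p = 0.302). The regions at chromosome 3, 94176879 to 94177016, and chromosome 7, 30969360 to 30969435 (mm9), were marked in 0 of 12 injured and 5 of 5 control libraries (Fisher's exact p = 0.000162). On chromosome 9 a region at 58883653 to 58884952 was marked in 1 of 12 and 5 of 5 libraries (Fisher's exact p = 0.00097, adjusted p = 0.302). At 7 to 28 d a region at 58883556 to 58884695 was marked in 3 of 14 and 8 of 8 (Fisher's exact p = 0.00103, adjusted p = 1). A region at chromosome 17, 35958774 to 35960508, was marked in 12 of 12 injured and 1 of 5 control libraries (Fisher's exact p = 0.0021, adjusted p = 0.318). With the files of broad regions, 26 H3K4me3 regions were called, 3 higher and 23 lower.

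For H3K27ac at 24 to 72 h, 4341 regions gave 95 higher and 59 lower at an unadjusted p under 0.05 by Fisher's exact test (8 injured and 3 control libraries). A region at chromosome 19, 45122360 to 45123037, was marked in 8 of 8 and 0 of 3 libraries. A region at chromosome 16, 92466168 to 92466851, was marked in 0 of 8 and 3 of 3 (both Fisher's exact p = 0.00606, the smallest this design allows, adjusted p = 0.598). At 3 to 10 h the unadjusted counts were 40 higher and 36 lower of 2502 H3K27ac regions and 31 and 47 of 2116 H3K4me3 regions, and at 7 to 28 d 8 and 14 of 2781 and 70 and 81 of 5878. Pairs of an injured and a control library shared 63.6% of H3K4me3 regions at 24 to 72 h, against 64.4% between injured and 68.4% between control libraries. Genes at these positions were not looked up, because no annotation of mm9 was used here.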

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

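The test of differences between phases, its repeats in pairs of legs, with higher scores, without unplaced sequence, with each leg left out and without the libraries whose labels disagree, were chosen after the peak numbers had been seen. In 34 groups of 4 to 10 legs, 7 legs lay far from the rest of their group by Dixon's test at the 95% level, and chance puts about 1 in 20 groups apart.

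Of these legs, 5 were H3K4me1 legs. Control replicate 4 at 14 d held 74 regions, against 695 to 1054 in the other 3 legs. Injured replicate 2 at 14 d held 432, against 741 to 794. Control replicate 3 at 7 d held 8, against 298 to 364. Control replicate 2 at 72 h held 4678, against 599 to 758. Injured replicate 1 at 72 h held 43063, against 758 to 851 in the other 4 legs. For H3K4me3, injured replicate 1 at 21 d held 31398 peaks, against 21823 to 21873, and injured replicate 2 at 24 h held 939, against 11438 to 23945.

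The injured minus control difference in the number of H3K4me1 regions differed between 2 phases, in libraries most of which held few regions. Under 1100 regions were held by 25 of 34 libraries at 24 to 72 h and 37 of 38 at 7 to 28 d, with a median of 32.2% and 32.1% of regions on unplaced sequence. At least 2000 regions were held by 2 of 24 injured and 5 of 10 control libraries at 24 to 72 h. At 7 to 28 d 1 of 20 injured and 0 of 18 control libraries did. The difference in log10 was -0.424 at 24 to 72 h, with the injured leg lower in 4 of 7 pairs and at 0.0322 with regions scored at least 5, and 0.368 at 7 to 28 d, with the injured leg higher in 9 of 14 pairs. The change of 0.791 over 53 legs gave a permutation p of 0.00463 and an adjusted p of 0.0417 over the 9 differences between phases, where the next adjusted p was 0.229. Without the regions on unplaced sequence it was 0.850 (permutation p = 0.00507, adjusted p = 0.0456), but it did not pass the adjustment in 3 other settings. From the differences of the 7 and 14 animals with both legs (replicate block) it was 0.924 (exact permutation p = 0.0118, adjusted p = 0.095). With regions scored at least 5 it was 0.359 (permutation p = 0.112, adjusted p = 0.261), and leaving out the 28 d libraries whose labels disagree 0.731 (46 legs, permutation p = 0.0147, adjusted p = 0.132). With each leg left out in turn it lay between 0.665 and 0.930, and the adjusted p was at least 0.05 for 31 of the 53 legs. The adjusted p was highest, at 0.156 and 0.144, without control replicates 3 and 4 of 24 h, and lowest, at 0.00135, without injured replicate 1 of 72 h.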

How the results depend on the processing

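The fits of only the 3, 24 and 48 h or the 72 and 168 h libraries, those without the 48 h libraries, the limit on the log2 change, the miRNA read test, the files of broad regions, the libraries whose labels disagree and the repeats of the difference between phases were alternatives chosen after seeing the data. Of 300 alternatives for 30 results, 270 kept the result, 2 were weaker, 1 stronger, 25 moved by over 1.5 times and 2 reversed. The 300 include alternatives of the region comparisons, which called 0 regions. In most of these comparisons almost no region could have passed the adjustment, so a count of 0 that was kept there says little. A count was kept if its total lay within 1.5 times, whatever the direction of the calls. A difference in peak number was kept if its direction and side of the threshold were. The share of higher genes was not weighed. With quantile normalization it went from 34% to 56.4% at 24 h and from 22.2% to 63.5% at 48 h. Of 479 named gene changes, 366 kept their call under every alternative run, and of 9683 alternatives 510 lost it and 5 reversed. The cause of a change was not tested unless given here. The 24 h against 3 h count of 5371 genes was 2705 in a fit of the 3, 24 and 48 h libraries and 1227 with only these 2 groups, and 2917 with a log2 change of at least 1. The same limit left 5207 genes at 48 h and 428 for 168 h against 72 h. With only the 72 h and 168 h libraries in the fit, that last count was 6888 of 12917 genes tested. Leaving out each library in turn gave 522 to 2023 there, 12330 to 14225 over time, 4224 to 6708 at 24 h, 6366 to 9337 at 48 h, 9451 to 12391 at 72 h and 9733 to 12515 at 168 h, where the lone sample is assumed to vary like the other groups. RNA replicate numbers did not pair the samples (correlations of -0.011 to 0.119), and with the replicate block the counts were 13277 over time, 5025, 7719, 11153 and 11365 against 3 h and 1058 for 168 h against 72 h, with 58 list calls. The 58 list calls were 23 with an estimated correlation and 101 with fry, which tests whether a list moves and not whether it moves more than other genes, 50 without the 48 h libraries and 61 with a pseudocount of 0.1. Genes that reversed at 48 h were Mcm4 (0.32), Bop1 (0.0116), Uhrf1 (0.49) and Cspg4 (0.39) with quantile normalization and Fbln1 (0.11) with median-of-ratios scaling.

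For miRNA, the exact binomial test on recovered reads called 119 at 3 h, 125 at 10 h, 146 at 72 h, 134 at 7 d, 135 at 14 d, 133 at 21 d, 133 at 28 d and 120 in the 28 d control. With the 28 d control as reference, the miRNAs at least 2-fold apart numbered 38 in place of 23 at 10 h and 34 in place of 53 at 28 d, and the let-7 median reversed to -0.06 at 3 h, -0.08 at 10 h and -0.21 at 7 d. With the files of broad regions, the H3K27ac difference at 24 to 72 h was -0.783 (exact permutation p = 0.0183) and 26 H3K4me3 regions were called. In paired legs of the same animal (replicate block), the 7 to 28 d difference reversed to 0.0947 for H3K27ac (13 pairs, permutation p = 0.656) and was 0.393 for H3K4me1 (permutation p = 0.0533), and the pairing ended the call of the H3K4me1 difference between phases (0.924, adjusted p = 0.095) but changed no other call. Leaving out libraries whose labels disagree gave 0.307 (permutation p = 0.0707). With peaks scored at least 5, the H3K4me1 difference at 24 to 72 h reversed to 0.0322. Leaving out each control leg of 24 to 72 h in turn, but no injured leg, gave -0.898 to -0.748 for H3K27ac and -0.360 to -0.231 for H3K4me3. The planned promoter windows and promoter gene lists were not run, as they need an annotation of mm9, nor were paired region tests of H3K27ac, or of H3K4me3 at 3 to 10 h, which had too few pairs. TPM keeps no depth, so no limit from depth can be set for RNA, and the 21 d miRNA library, with 165753 reads, was the least precise.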

Other observations

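The tests of the 48 h libraries with fast-evolving and slow-evolving gene lists were written before the result was seen. All other tests weighed here were chosen after it, as were the use of unadjusted p in the splits and the reading of the slow-evolving list as undecided. Several gene groups not described so far also moved in the satellite cell libraries. Interferon response genes fell in 9 and rose in 1 of 15 cases at 24 h against 3 h (adjusted over the list alone, 10 and 1; camera adjusted p = 0.0111, and adjusted p = 0.166 with an estimated correlation). At 48 h 12 fell and 0 rose (camera adjusted p = 0.0108 and 0.166), although 2 rose with either other scaling and only 6 fell with quantile normalization. Those falls lay in the libraries that listed many abundant genes near 0. Ifit1, an interferon-induced antiviral gene, had log2 changes of -1.78 ± 0.16 and -3.37 ± 0.16 (SE, n = 2 per group). At 72 h 6 rose and 4 fell (adjusted p = 0.734), with Irf7, a transcription factor of the interferon response, at 2.28 ± 0.37. Histone and DNA modifiers rose in 8 of 20 cases at 24 h (adjusted p = 0.000836 and 0.0693), and 7 rose and 2 fell at 48 h, 7 and 1 adjusted over the list alone (adjusted p = 0.00119 and 0.0708), where 12 rose with median-of-ratios scaling and 15 with quantile normalization. At 72 h they split, 7 up and 9 down (adjusted p = 0.771). Uhrf1, which brings DNA methyltransferase to replicated DNA, rose by 5.77 ± 0.35 and Dnmt1, that methyltransferase, by 3.33 ± 0.17, while Kdm6a, a demethylase of H3K27, fell by 3.48 ± 0.08 and Ezh2, a methyltransferase of H3K27, by 0.67 ± 0.05. Of 6 lymphocyte genes 1 rose and 3 fell at 72 h (adjusted p = 0.612), with Cd3d, a subunit of the T cell receptor complex, at -4.42 ± 0.27. Of 4 adipocyte genes, too few for a list test, 1 fell from 72 h to 168 h, Fabp4, a fatty acid carrier, at -1.25 ± 0.16.

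Among miRNAs, each with 1 sample per time, miR-205-5p stood at 7.19 (log2 against the 3 h control, 95% counting interval 6.46 to 9.04) and miR-203-3p at 4.77 (4.42 to 5.26) at 7 d, both miRNAs of epithelium. The 9 measured miRNAs of the list of the imprinted Dlk1-Dio3 and H19 loci, all of Dlk1-Dio3, had a median of -0.69 at 3 h, lower than all but 0.2% of random lists, and -0.83 at 10 h (0.1%). The 5 vascular miRNAs stood at -0.62 at 3 h (2.1%) and -0.94 at 28 d (3.2%). The 10 let-7 miRNAs stood at 0.40 at 3 h, above 99.3% of random lists, and 1.05 at 28 d (99.9%), but also at 0.51 in the 28 d control, and with that control as reference the median at 3 h was -0.06. The 90 H3K4me1 libraries held 8 to 43126 regions with a median of 723 and covered 0.004 to 45.2 Mb. In the 73 libraries under 1100 regions a median of 32.5% of regions lay on unplaced sequence, against 0.59% in the 15 with at least 2000, of which 8 were injured and 7 control. Repeat lanes with the same animal label differed by up to 21.5 times for H3K27ac and up to 1.92 times for H3K4me3, and for H3K4me1 by most in a 48 h control leg, with 789 and 11801 regions. The libraries of the 7 d numbers 04 and 04B, joined as 1 leg, ranged from 148 to 22546 H3K4me3 peaks in the injured and from 677 to 24761 in the control leg.

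In the 48 h RNA libraries, 1498 of 7413 genes expressed at 72 h and 168 h (20.2%) lay under 1 TPM. Low depth, an explanation narrowed from low depth or loss of RNA after its value was seen, is argued against, since 82.6% of the abundant genes under 5 TPM in either library were so in both (71 of 86). Regulation in the satellite cells as the whole account is argued against by an SD over 78 ribosomal protein genes of 3.79 for log2(48 h / 72 h), against 0.06 at 168 h but also 1.70 at 3 h and 1.71 at 24 h, and among earlier libraries of 2.34 for log2(48 h / 24 h) against 0.29 for log2(24 h / 3 h). Reads from another organism, which would match fast-evolving genes least, may account for part. Of fast-evolving genes 36.2% (17 of 47) were near 0 against a median of 14.9% in random lists, and 71.4% of rodent-lineage genes (5 of 7) against 14.3%. The random lists were matched only on mean TPM at 72 h and 168 h. Which cells made the listed genes was not tested, so a change in the cells present could give the same excess. The same shares at 3 h and 24 h were not computed. At 48 h 22 of 78 ribosomal protein genes also lay under 10 TPM, which was not weighed against this account. The slow-evolving list decides nothing, since at 3.8% (1 of 26) it lay under the random median of 11.5% but missed a bound that only 0 of 26 would have met, as do the conserved genes (0 of 33, against 6.1%), and the pattern stays open.

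The 72 h control files of broad regions may account for the H3K4me3 regions called at 24 to 72 h, but this could not be decided. With them 26 were called and without them 0, where 444 lay at an unadjusted p under 0.05 by Fisher's exact test. Leaving them out also cut the control legs from 8 to 5. The smallest possible p was then 0.000162 over 5908 regions, so few regions could have passed. The type of file cannot be told apart here from the loss of control legs. The files of broad regions do not account for the lower number of H3K27ac peaks, a log10 difference of -0.83 without them and -0.783 with them. With 3 control legs the exact permutation p was nevertheless 0.139, and 0.107 in a permutation within flow cells. A biological difference between injured and control legs stays open, because these tests rest on few control legs whose times differed from those of the injured legs. Peak numbers were also not adjusted for sequencing depth or the quality of the ChIP. The injured leg of replicate 1 at 48 h gave 1132 and 24376 H3K27ac peaks in its 2 lanes. The median ratio between repeat lanes was 1.035 over 16 H3K27ac legs.

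The fall of matrix and fibro-adipogenic genes from 72 h to 168 h came with markers of other cells in the same libraries. A smaller share of fibro-adipogenic cells alone would lower all their genes alike only if no other cell in the libraries made them. The log2 changes spread over 3.22 between Dpt and Ly6a, where the larger SE was 0.18. This spread cannot decide, since it was not tested which cells made each gene. Scaling of the libraries is argued against, since 18 of 18 matrix genes that fell stayed called under both other scalings, as did 6 of 7 fibro-adipogenic genes. A smaller share of these cells, a change of expression with time, or both may remain, and they were not told apart here.

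Regions at an unadjusted p under 0.05 were counted over other splits of the same libraries. Chance was argued against at a share under 0.05, without adjustment over the 6 comparisons, for H3K4me3 at 24 to 72 h. The real split gave 444 there (1 of 100, the real one, highest other 388). A share of 1 of 100 is the smallest that 100 drawn splits can give. There 1 of 100 splits also gave as many among those that kept the numbers per time (highest other 279), per flow cell (342) or parted all 4 pairs of legs (347). H3K27ac in that phase gave 154, as many as in 1 of 100 freely drawn splits (highest other 131). Chance was not excluded there when the times were kept (2 of 40) or both pairs parted (2 of 28), where another split gave 283, although 2 of 75 splits gave as many within flow cells. H3K27ac at 3 to 10 h gave 76 (2 of 56, highest other 90), in 1 of 30 splits with times kept (highest other 58) but 2 of 16 that parted both pairs, where chance was not excluded. With flow cells kept there were only 4 splits, too few for a share under 0.05 (highest other 42). Chance was not excluded for the other 3 comparisons. At 7 to 28 d H3K27ac gave 22 (22 of 35, highest other 82), so the highest other split gave several times the real count, which points to a structure of these libraries. The highest other was 29 with times kept (6 of 9), 37 with flow cells kept (20 of 36) and 28 with both pairs parted (12 of 24). H3K4me3 at 7 to 28 d gave 151 (32 of 100, highest other 227). H3K4me3 at 3 to 10 h gave 78 (10 of 35, highest other 182). At 24 to 72 h the counts within flow cells were 165 for H3K27ac and 369 for H3K4me3, and those stratified by time 59 and 374.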
